A study of Mus musculus with 24 samples.

How the data were processed

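Single-cell RNA was measured in live cells sorted from tumour-bearing bone of 12 mice carrying LLC1, a Lewis lung carcinoma cell line, with 3 mice in each of 4 groups (LysM-ctrl and LysM-cre, female and male). In the LysM-cre mice Esr1, the gene of oestrogen receptor alpha, carries a conditional deletion driven from the Lyz2 (LysM) locus in myeloid cells. Per the labels, tissue was dissociated with collagenase A and cells were tagged with CellPlex oligonucleotides, pooled and sequenced as 3′ libraries. The authors processed the reads with Cell Ranger (version 7.2.0 in the matrix headers) against mm10 and named Seurat without a version. The deposited matrices hold a count of UMIs per gene and cell, and 2 barcode files per mouse give 24 files in all. All LysM-ctrl mice were in 1 library pool and all LysM-cre mice in the other, so genotype and pool cannot be told apart, while both sexes were present in each pool.

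The 2 files of a mouse were treated as technical replicates and summed. Across their class counts, the 2 files of a mouse differed with a chi-square per degree of freedom of 2.75 to 7.77 (median 4.00), against 6.89 to 212.6 (median 41.4) for files of 2 mice of a group. Cells with at least 200 detected genes and at most 10% of UMIs from mitochondrial genes were kept. This kept 45031 of 45704 cells, between 2814 and 5347 per mouse. Each file lists 32285 mouse gene IDs, of which 32235 were matched to the GENCODE vM21 annotation, together with 3 added sequences and 12 multiplexing tags.

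Cells of all files were clustered together in Python 3.11.15 with scanpy 1.11.5, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, umap-learn 0.5.12, igraph 0.11.9 and leidenalg 0.10.2. UMIs were scaled to 10000 per cell and log-transformed, 2000 variable genes were requested (1936 used), and 30 principal components, 15 neighbours and Leiden resolution 1.0 gave 28 clusters. Clusters with close scores for 2 cell types were sub-clustered, which gave 55. Each cluster took the name of the highest-scoring cell type that met the following conditions. At least 3 of the type's markers were detected in at least 10% of the cluster's cells. No other type had more markers among the cluster's 10 leading genes. A minimum score also applied, and clusters of low depth needed a marker of the type among these leading genes. No cell was removed as a doublet in the results reported first. Some clusters held a UMI of the added gfp sequence in at least 20% of cells but did not take the tumour name by these conditions. Such clusters were kept as a separate class, called the gfp-positive unnamed class.

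Class shares are percent of a mouse's kept cells. Genotype was tested with a two-sided exact permutation test of the difference in mean share averaged over the sexes, permuting mice within each sex (400 arrangements, smallest p 0.005). Sex was tested the same way within genotype. Within 1 sex the 3 mice against 3 allow 20 arrangements and no p below 0.1. Benjamini-Hochberg adjustment ran over the 19 named classes and over 10 T-cell sub-clusters.

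Genes were tested on UMIs summed per mouse and class, for classes in which the groups had enough cells. Mice with fewer than 20 cells of a class were left out of its tests. edgeR 4.0.16 in R 4.3.3 was used with TMM normalization, filterByExpr and the quasi-likelihood F test on 4 groups, and Benjamini-Hochberg adjustment at 0.05. The genotype contrast is the LysM-cre minus LysM-ctrl difference averaged over the sexes, and the interaction is the male minus the female genotype difference. CPM ranges over mice, CPM of single mice, group means of Tmsb4x and summed Y-linked genes are scaled by the total UMIs of a class. Other group means in CPM are scaled by the TMM library size. Fold changes are on the log2 scale with their standard error (SE). Gene lists were tested with camera in limma 3.58.1 at an inter-gene correlation of 0.01, adjusted over the lists of a class, with camera at an estimated correlation and fry as alternatives. The lists were oestrogen response, alternative and immunosuppressive macrophage, inflammatory macrophage, type I interferon response, interferon gamma response, MHC class I and class II presentation, chemokines, complement and efferocytosis, lipid handling, matrix remodelling, osteoclast genes, hypoxia and glycolysis, oxidative phosphorylation, proliferation, cytotoxicity, T cell exhaustion, naive and memory T cell, regulatory T cell, tumour-associated neutrophil, epithelial to mesenchymal transition and dissociation stress. The share of cells with an Esr1 UMI was taken after thinning each cell to 2000 UMIs, with exact Clopper-Pearson intervals at 95% that cover counting error only. Figures were drawn with matplotlib 3.10.9.

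The lists, the tests and the rule for named genes were fixed beforehand. Named genes of a class are Esr1 and Lyz2, the 10 (macrophage) or 5 (other classes) genes with the largest fold change in each direction among those past 0.05 with a mean log2 CPM of at least 4 and 1 sign in both sexes, and up to 4 members of each list with the smallest adjusted p. For the interaction and the sex contrast they are the 5 largest in each direction past the threshold. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, T-cell receptor, Gm, Rik and sex-linked genes were left out of the second part. Genes named outside this rule are stated as such. In neutrophils 1 gene that the rule names is not reported here.

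Other settings chosen before the data were examined were a stricter filter (500 genes and 5% mitochondrial UMIs), removal of cells with a Scrublet score above 0.25, Leiden resolutions 0.5 and 2.0, each barcode file alone, each mouse left out in turn, an edgeR test of cell counts, immune cells as the denominator, DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, limma-voom, no filter on low counts, at least 10 counts per mouse on average, 1 sex alone and no thinning. Added after the data were seen were the removal of mice m313 and m323, both gfp-positive clusters as 1 class, an exact permutation test of each list's mean log2 CPM per mouse, and the Esr1 share expected over all random thinnings. The edgeR test was tested on simulated data with the groups, sizes and spread of each class. It recovered between 64.3% (T cell) and 87% (monocyte) of genes changed by 1 log2 unit, and between 95% (tumour) and 100% of those changed by 2. Of the simulated genes called, between 4.15% (neutrophil) and 7.43% (monocyte) had not been changed. The genes were simulated independently of each other, so these shares do not cover correlation between genes or differences between mice that genes share.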

Results

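The series compares LLC1 Lewis lung carcinoma growing in bone between mice with a conditional deletion of Esr1 intended for LysM-expressing myeloid cells (LysM-cre) and LysM-ctrl mice, in both sexes. It holds 3′ single-cell counts from 12 mice, with 3 mice per genotype and sex (LysM-ctrl female mice m306, m307 and m309, LysM-ctrl male mice m319, m320 and m324, LysM-cre female mice m315, m317 and m323, LysM-cre male mice m311, m313 and m314). Kept cells carried between 17195318 (mouse m313) and 44711701 (mouse m315) UMIs per mouse. The median UMIs per cell ranged from 4590 (mouse m320) to 5874 (mouse m317) over the mice. The 45031 cells fell into neutrophils (15490 cells), neutrophil precursors (10914), monocytes (7292), a gfp-positive unnamed class (3057), conventional dendritic cells (1518), tumour cells (1094), B cells (1014), T cells (882), macrophages (757), plasmacytoid dendritic cells (746) and smaller classes. The tumour class was led by Hmga2, Il1rl1, Mmp3 and Rhox5. The gfp-positive unnamed class was led by Ptn, Ghr, Col3a1, Lum and Prrx1, which include genes of fibroblast-like cells. The added gfp sequence was found in 41.81% of its cells and in 55.21% of those of the tumour class. In male mice its Xist and Y-linked transcripts, given below, argue against a host origin. The tumour class may therefore hold only a part of the tumour cells, and its share is not read as that of the whole tumour. The 2 pools coincide with the genotypes, so every genotype difference below is also a difference between pools. In males, higher levels of genes at the distal end of chromosome X, described below, also went with the genotype in 6 of 6 mice. Genotype differences in males, and averages over the sexes, cannot be told apart from that difference either.

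The first question is whether Esr1, the deleted gene, and Lyz2, the locus that carries the recombinase, differ between the genotypes. Lyz2 transcripts, which encode the lysozyme of myeloid cells, were lower in LysM-cre mice by a log2 change of -1.05 (SE 0.03) in monocytes, -1.06 (SE 0.08) in neutrophils and -1.40 (SE 0.17) in macrophages. In monocytes the LysM-cre mice ranged from 6865 to 7504 Lyz2 CPM (UMIs scaled to a common library size, n = 6) and the LysM-ctrl mice from 13755 to 15311 (n = 6), without overlap. Esr1 levels did not differ by edgeR in macrophages (-0.01, SE 0.35, adjusted p 0.999), monocytes (0.11, SE 0.10, adjusted p 0.651) or neutrophils (0.04, SE 0.16). After 1 random thinning, an Esr1 UMI was found in 8.07%, 4.76% and 3.51% of macrophages of LysM-ctrl females m306, m307 and m309, and in 3.88%, 2.41% and 7.14% of those of LysM-ctrl males m319, m320 and m324. The share was 1.02% and 6.12% in LysM-cre females m315 and m317 and 2.97% in LysM-cre male m314. No Esr1 UMI was seen in 46 thinned macrophages of LysM-cre male m311 (upper 95% limit 7.71%, Clopper-Pearson), nor in the 4 cells each of mice m313 and m323 (upper limit 60.2%). The mean share was 4.96% ± 2.20 (SD, n = 6) in LysM-ctrl and 1.69% ± 2.46 (SD, n = 6) in LysM-cre mice, a difference of -3.28 points with a two-sided exact permutation p of 0.05, which is not under the 0.05 threshold. The difference depended on the random draw, since the share expected over all thinnings, an alternative chosen after the data were seen, was 4.36% ± 1.18 in LysM-ctrl and 3.47% ± 2.33 in LysM-cre mice (SD, n = 6; -0.89 points, exact p 0.42), with 3.49% in mouse m311. With the stricter cell filter, which drew anew, 3 of 46 cells of m311 held Esr1 (6.52%) and the difference was -2.35 points (exact p 0.14). It was -2.43 points (exact p 0.17) without mice m313 and m323 and 2.62 points (exact p 0.36) without thinning. With single mice left out the p fell below 0.05 without m317 (-4.21 points, exact p 0.015), m314 (-3.77 points, exact p 0.035) or m320 (-3.79 points, exact p 0.04) and was 0.05 to 0.095 without any 1 of the others. In classes set beside these, Esr1 was found after thinning in 2.32% of T cells, 1.21% of neutrophils, 4.29% of monocytes, 7.11% of tumour cells and 15.9% of B cells. In the gfp-positive unnamed class, which was not thinned, Esr1 was found in 74.51% (female mice) and 74.96% (male mice) of cells. Its level there was 147.87 and 149.38 CPM, against 26.37 and 22.47 CPM in macrophages. How much of the Esr1 in any class is free RNA was not measured. Before thinning the median depth was 6123 (female) and 6457 (male) UMIs in macrophages, 4626 and 4796.5 in T cells and 3084 and 2954 in neutrophils. A 3′ tag that lies outside the deleted part of Esr1 (chromosome 10, 4611593 to 5005614) does not check the deletion.

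**Figure D1:**
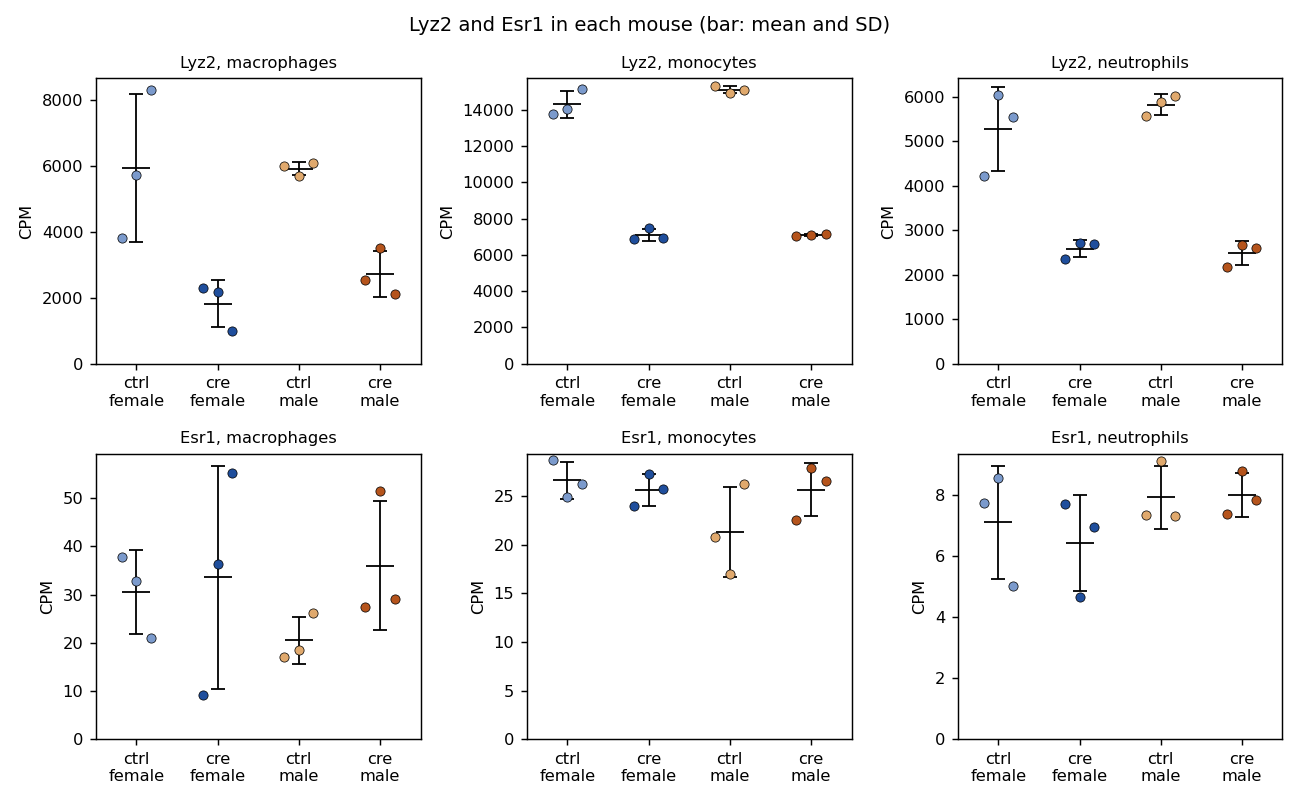
Lyz2 (upper panels) and Esr1 (lower panels) in CPM in macrophages, monocytes and neutrophils by group, with 1 point per mouse and the group mean and SD as a bar. In monocytes the 6 LysM-cre mice lie between 6865 and 7504 Lyz2 CPM, below the lowest LysM-ctrl mouse at 13755, while the Esr1 values of the genotypes overlap.

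Cell composition was compared to ask which cells of the tumour-bearing bone differ with the genotype. Neutrophils made up 38.6% ± 4.61 (SD, n = 6) of cells in LysM-ctrl and 30.6% ± 4.38 (SD, n = 6) in LysM-cre mice, a difference of -8.05 points that was nearly equal in females (-8.16) and males (-7.94). T cells were 1.68% ± 0.916 in LysM-ctrl and 2.17% ± 0.446 in LysM-cre mice. Monocytes were 15.4% and 16.8%, neutrophil precursors 22.7% and 25.8%, macrophages 1.95% ± 0.842 and 1.43% ± 1.11, tumour cells 2.29% and 2.56%, and the gfp-positive unnamed class 5.74% ± 2.28 and 7.96% ± 6.16. LysM-cre mice m313 and m323 held few cells of the last 3 classes and lower these LysM-cre means. The same 2 mice raise the LysM-cre mean of neutrophil precursors, with 33.0% and 32.8% (other mice 16.8% to 28.1%). The other LysM-cre mice held 1.49% to 2.99% macrophages (LysM-ctrl 0.821% to 3.34%). They held 3.02% to 4.87% tumour cells (LysM-ctrl 1.23% to 3.10%) and 6.36% to 14.3% gfp-positive unnamed cells (LysM-ctrl 2.77% to 8.53%). Bone-resorbing osteoclasts were 0.309% ± 0.199 in LysM-ctrl and 0.164% ± 0.178 in LysM-cre mice (SD, n = 6, exact permutation p 0.195). Mice m313 and m323 held 0 of them, which lowers the LysM-cre mean. None of the 19 classes passed the exact permutation test after adjustment. Over 19 classes 1 class alone at the smallest p of 0.005 could not have passed, so this count does not show equal shares. Neutrophils alone had an unadjusted exact p under 0.05 (exact p 0.01, adjusted p 0.19), and T cells followed (exact p 0.09, adjusted p 0.534). By edgeR on cell counts the neutrophils had a log2 change of -0.34 for neutrophils (adjusted p 0.071) and no class passed. In T cells the male difference was 0.917 points (0.924% ± 0.264 against 1.84% ± 0.284, n = 3, exact p 0.1, the smallest possible) and the female difference 0.069 points (exact p 0.9). The difference between those differences, 0.848 points, had an exact permutation p of 0.145.

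**Figure D2:**
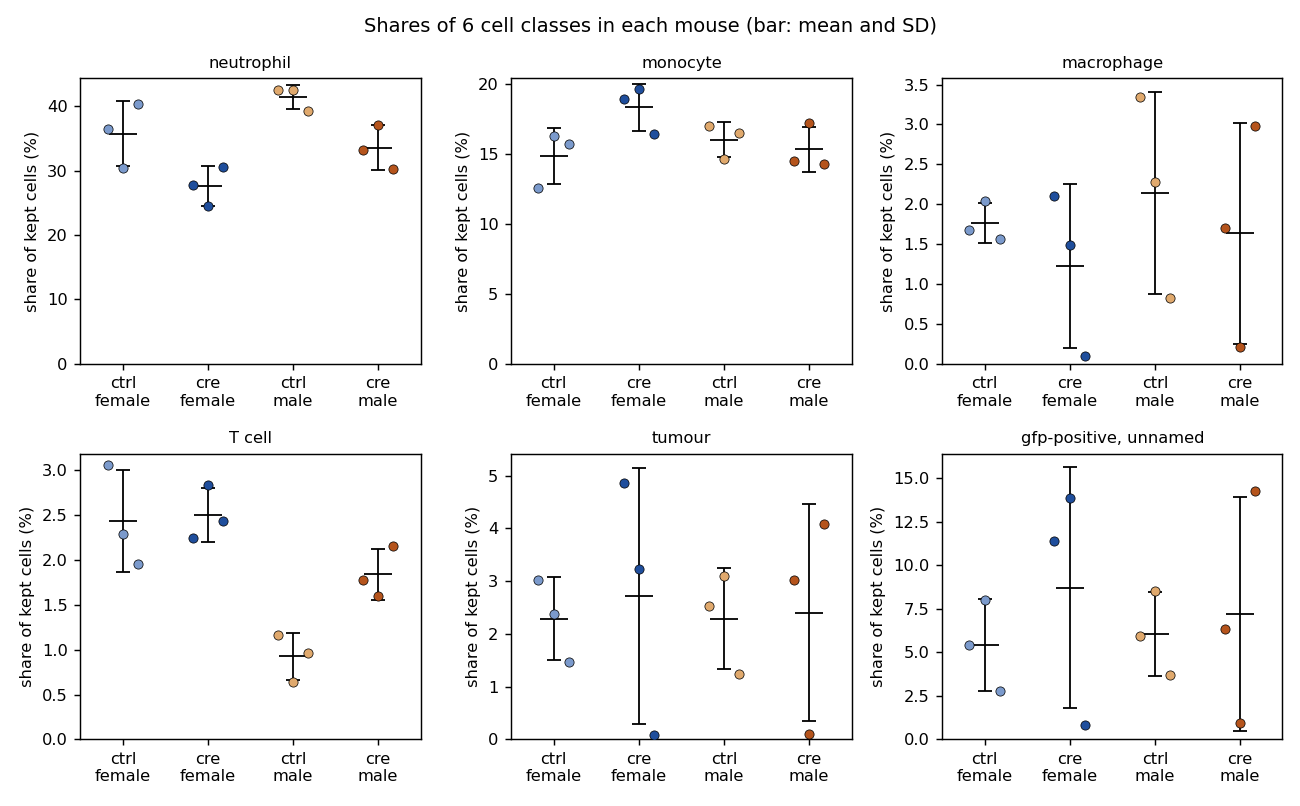
Share of kept cells per mouse in percent for neutrophils, monocytes, macrophages, T cells, tumour cells and the gfp-positive unnamed class by group, with 1 point per mouse and the group mean and SD as a bar. Neutrophil shares average 38.6% in LysM-ctrl and 30.6% in LysM-cre mice, and T-cell shares 2.47% in females and 1.38% in males.

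Between the sexes, T cells and natural killer cells differed. T cells made up 2.47% ± 0.406 (SD, n = 6) of cells in females and 1.38% ± 0.559 (n = 6) in males, and natural killer cells, the innate cytotoxic lymphocytes, 1.08% ± 0.288 and 0.529% ± 0.170. Both differences passed the exact permutation test within genotype (T cells -1.085 points, natural killer cells -0.551 points, each exact p 0.005, the smallest possible, adjusted p 0.0475), and they were the 2 of 19 classes to do so. At Leiden resolution 2.0 neither passed (T cells -0.4 points, adjusted p 0.253, natural killer cells -1.285 points, adjusted p 0.095), nor with barcode file 1 alone (adjusted p 0.19 and 0.2375) or barcode file 2 alone (0.095 for both). B cells, the other lymphocytes, were 2.90% and 1.37% and did not pass (exact p 0.06, adjusted p 0.285). Neutrophils were 31.7% in females and 37.5% in males (5.81 points, exact p 0.02, adjusted p 0.127). By edgeR on cell counts T cells passed (adjusted p 0.036) and natural killer cells did not (adjusted p 0.066). The count of 2 fell to 0 without any 1 of mice m306, m307, m320, m324, m311, m313, m314, m317 and m323.

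Within the T cells, sub-clusters were compared to ask whether a T-cell type shifts with the genotype. A CD4-positive sub-cluster in which 79.6% of cells held Ctla4 and 16.1% Foxp3, the regulator of regulatory T cells, made up 10.3% ± 5.60 of T cells in LysM-ctrl and 10.8% ± 6.95 in LysM-cre mice (SD, n = 6). A sub-cluster in which 49.4% of cells held the gamma-delta receptor gene Trdc, 42.4% Il2ra, 41.2% Cd163l1, 27.1% Il17a and 10.6% Foxp3 made up 12.04% ± 4.59 and 7.04% ± 5.31. A sub-cluster with Cd8a in 29.1% and Ikzf2 in 77.7% of cells made up 9.07% ± 2.86 and 14.0% ± 5.46. None of the 10 sub-clusters passed the exact permutation test, and the smallest p was 0.105 (adjusted p 0.533), for the sub-cluster just named. Over 10 sub-clusters 1 alone at the smallest possible p of 0.005 could not have passed either. The T-cell receptor gene Cd3e was found in 54.3% to 96.2% of the cells of a sub-cluster. In the sub-cluster at 54.3%, Cd4 was found in 0%, Cd8b1 in 1.9% and Ikzf2 in 78.1% of cells. Whether the T-cell class also holds other lymphocytes was not tested.

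Macrophages, the cells in which the deletion was intended, showed few gene differences between genotypes. Lyz2 fell by 1.40 (SE 0.17, adjusted p 0.0015), from 6254 and 6146 CPM in LysM-ctrl females and males to 2258 and 2431 CPM. Lyz1 (chromosome 10, 117287797 to 117292868), its neighbouring and nearly identical paralog, rose by 5.10 (SE 0.44, adjusted p 3.0e-05), from 0.793 and 14.3 CPM to 58.8 and 183.5 CPM, and reads of the paralogs may be assigned to either. Sox5, a transcription factor, rose by 5.14 (SE 0.81, adjusted p 0.048) and Negr1, a neural adhesion gene, by 3.75 (SE 0.64, adjusted p 0.048), although Sox5 had no UMI in any LysM-ctrl male, so that its fold depends on the prior count. Gm47283 (chromosome Y, 90784738 to 90816464), a gene model named here after its values were seen, rose by 5.38 (SE 0.30, adjusted p 1.4e-07) with similar levels in LysM-cre females (215.6 CPM) and males (141.6 CPM). These 5 genes, 4 up and 1 down, were all that passed of 6463 tested in 10 mice, since mice m313 and m323 had fewer than 20 macrophages. 379 genes had an unadjusted p under 0.05, DESeq2 called 10 and limma-voom 5. The call of Sox5 ended without any 1 of mice m306, m307, m309, m319, m320, m324, m315 and m311 (adjusted p up to 0.20 without m319), that of Negr1 without any 1 of m307, m319, m320, m324, m315, m311 and m314 (up to 0.22 without m319). The Lyz2 call ended at Leiden resolution 2.0 (adjusted p 0.42), and the Lyz1 call at resolution 0.5 (adjusted p 0.86) and with the first barcode file alone (0.83). The count was 3 without mouse m307, m319, m320 or m311 and 11 without mouse m315.

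Among the gene lists in macrophages, the interferon gamma response was higher in LysM-cre mice in all 17 measured members (median log2 change 0.66; 9 of 17 in females, median 0.03, and 17 of 17 in males, median 1.09), such as Gbp2 (0.83) and Ciita (0.79), the activator of MHC class II genes. The list passed camera (adjusted p 2.5e-06) but had adjusted p = 0.736 with an estimated correlation. MHC class II presentation was positive in 8 of 9 members (median 0.48), with log2 changes of 0.81 for H2-Eb1, 0.72 for H2-Aa and 0.71 for H2-Ab1. Its camera adjusted p was 0.0014, with adjusted p = 0.736 with an estimated correlation, and was 0.091 without mouse m317. No member of either list passed over all genes, while 1 interferon gamma and 3 class II members passed adjusted over the list alone. The other lists did not pass: oestrogen response (4 of 10 positive, median -0.08, mean 0.07 and camera upward), alternative and immunosuppressive macrophage (6 of 21), inflammatory macrophage (9 of 18, median 0.00, mean -0.04 and camera upward), type I interferon (7 of 14, median -0.01, mean 0.00), MHC class I (14 of 16, adjusted p 0.163), chemokines (6 of 18), complement and efferocytosis (10 of 16), lipid handling (8 of 20), matrix remodelling (4 of 17), osteoclast genes (1 of 7), hypoxia and glycolysis (5 of 22), oxidative phosphorylation (19 of 40), proliferation (11 of 15) and dissociation stress (12 of 20). Spp1, an osteopontin gene of tumour macrophages, had a log2 change of -1.16, Arg1 -0.61, Mmp9 -1.49 and Ccl5 1.30, none past the threshold.

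The genotype effect in macrophages was also read in each sex. In females 5 genes passed (4 up, 1 down), namely Gm47283 (5.89), Lyz1 (5.79), Lyz2 (-1.47), the early response gene Egr1 (1.82, adjusted p 0.014) and Retnla, a gene of alternative activation at 128.1 CPM in LysM-cre females and at 0 in LysM-ctrl females. In males 12 passed (10 up, 2 down), including Pecam1 (2.29), Tmsb4x (0.94), Fcgr4, an activating Fc receptor (1.96, adjusted p 0.016), Olr1, a scavenger receptor (-1.42), Lyz1 (4.40) and Lyz2 (-1.34). Retnla, Pecam1, Tmsb4x and Olr1 were chosen after their values were seen. The interaction of genotype and sex gave 0 genes by edgeR, with 358 at an unadjusted p under 0.05, against 3 by DESeq2 and 0 by limma-voom. For Egr1 the interaction was -2.51 (adjusted p 0.081) and for Fcgr4 2.09 (adjusted p 0.28), so neither was shown to differ between the sexes. The female count was 3 without mouse m306 and 2 without mouse m307 or m315, the male count 3 without mouse m319, 5 without m320, 7 without m311 and 4 without m314, and the interaction count 7 without mouse m309 and 1 without mouse m324, m315 or m314.

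Macrophages of males and females differed in few genes. Apoe, the apolipoprotein of macrophage lipid export, was higher in males by a log2 change of 1.35 (SE 0.15, adjusted p 2.8e-04), with 929 CPM in LysM-ctrl females, 1654 in LysM-ctrl males, 732 in LysM-cre females and 2682 in LysM-cre males. Pltp, a phospholipid transfer protein, was higher by 1.12 (SE 0.19, adjusted p 0.031) and Gpnmb, a gene of lipid-laden macrophages, by 3.28 (SE 0.52, adjusted p 0.014). The other 5 of 8 genes past the threshold (6 up and 2 down in males) were the sex-linked Xist, Tsix, Uty, Ddx3y and Eif2s3y. By unadjusted p under 0.05 there were 388. The mix of clusters within the class also differed. In females 1 cluster held 13.5% (LysM-ctrl) and 17.1% (LysM-cre) of macrophages, and in males 26.6% and 36.7%. A different mix of cells was thus not told apart from a change within them. The lipid handling list did not pass between the sexes (10 of 20 members higher in males, median 0.08, camera adjusted p 0.193). The Gpnmb call ended without mouse m315 (adjusted p 0.10) or m314 (0.072), and the Pltp call without any 1 of mice m306, m309, m315, m317, m311 and m314 (up to 0.17 without m315). The Apoe call held without each mouse in turn but not with the second barcode file alone (adjusted p 0.19), and the count was 18 without mouse m317.

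Under the settings reported first, monocytes gave the most genotype differences of the 6 classes described here. This rank did not hold under all settings, such as Leiden resolution 0.5, where neutrophils gave more. Lyz2 fell by 1.05 (SE 0.03, adjusted p 8.0e-12) and Lyz1, its paralog, rose by 4.19 (SE 0.57, adjusted p 0.0012). Hist1h2ap, a replication histone gene, rose by 0.88 (SE 0.08, adjusted p 8.8e-06). Genes of the distal X chromosome rose on average over the sexes, namely Tlr7, a sensor of single-stranded RNA, by 0.69 (SE 0.13, adjusted p 0.013), Tmsb4x, which encodes the actin-binding thymosin beta 4, by 0.52 (SE 0.03, adjusted p 2.7e-09), and Hccs, a mitochondrial cytochrome c synthase, by 0.52 (SE 0.07, adjusted p 0.0014). In males these rises were 1.18 (SE 0.18), 0.97 (SE 0.04) and 1.02 (SE 0.10), and in females 0.21 (SE 0.18), 0.08 (SE 0.04) and 0.01 (SE 0.10). Atp5b, a subunit of ATP synthase, fell by 0.28, Ms4a4a by 0.48 and Ier3 by 0.43, while the transcription factor Klf6 rose by 0.34. Vcan, a matrix proteoglycan of classical monocytes (-0.65, adjusted p 0.048), and the neutrophil chemokine Cxcl3 (-1.80, adjusted p 0.048) were just past the threshold. B2m, the light chain of MHC class I, rose by 0.21, and C5ar1, the receptor of complement C5a, fell by 0.34. In all, 135 of 11060 genes passed (74 up, 61 down), with 1660 at an unadjusted p under 0.05. The Vcan call held without mouse m306, m315 or m311 and ended without any 1 of the other 9 mice (adjusted p up to 0.15 without m317), the Cxcl3 call ended without any 1 of 10 mice (all but m320 and m315, up to 0.11), the B2m call without m307, m309, m319 or m317 (up to 0.073) and the C5ar1 call without m309, m319, m324, m317 or m313 (up to 0.073). The Tlr7 and Ms4a4a calls ended without mice m313 and m323 together (adjusted p 0.058 and 0.062). The count was 79 without mouse m307, 57 without m309, 40 without m319, 78 without m320, 71 without m324, 48 without m317, 74 without m323 and 70 without m313.

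Interferon genes as a group were higher in monocytes of LysM-cre mice on average over the sexes. By the signs of the members the rise was in males. The exact permutation test of the difference between the sexes did not pass for the type I list in this class alone. In the type I interferon response 25 of 26 members were positive (median 0.29, camera adjusted p 1.0e-04) and in the interferon gamma response 17 of 19 (median 0.29, camera adjusted p 0.0010), each with adjusted p = 0.912 with an estimated correlation. In females 6 of 26 (median -0.08) and 5 of 19 (median -0.22) were positive, and in males 26 of 26 and 19 of 19 (median 0.65 for both). No member of either list passed over all genes or adjusted over the list alone. Dissociation stress genes were positive in 14 of 20 (median 0.18), with 3 up (Klf6, Fos and Nr4a1) and 1 down (Ier3) over all genes and 6 up and 1 down adjusted over the list alone. Its camera adjusted p was 0.026 (adjusted p = 0.912 with an estimated correlation), 0.11 without mouse m306, 0.054 without m315 and 0.067 without m314. Singly, the Fos call ended without mouse m306, m319 or m317 and the Nr4a1 call without m306, m309, m319, m324, m317, m313 or m314. Hypoxia and glycolysis was positive in 6 of 21 (median -0.08), also with a camera adjusted p of 0.026 and adjusted p = 0.912 with an estimated correlation. That call ended without mouse m307 (0.11), m320 (0.11), m323 (0.12), m313 (0.22) or m314 (0.067). Oxidative phosphorylation (27 of 40 positive) did not pass (adjusted p 0.088), with 3 members up and 1 down over all genes and 6 up and 3 down adjusted over the list alone. Complement and efferocytosis (5 of 13 positive) had 1 member down over all genes and 3 adjusted over the list alone. The remaining lists did not pass, namely oestrogen response (6 of 10 positive), alternative and immunosuppressive macrophage (7 of 13), inflammatory macrophage (10 of 18, median 0.03, mean -0.04), MHC class I (11 of 17), MHC class II (5 of 9, median 0.00, mean 0.11, camera downward), chemokines (10 of 13), lipid handling (8 of 18, median -0.01, mean 0.04), matrix remodelling (9 of 16, median 0.01, mean 0.02, camera downward), osteoclast genes (5 of 6) and proliferation (13 of 23).

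Neutrophils of LysM-cre mice had more S100a8, the calprotectin subunit, by 0.40 (SE 0.04, adjusted p 8.0e-05), and less Lyz2 by a change of -1.06 (SE 0.08, adjusted p 1.4e-06). Tmsb4x rose by 0.54 (SE 0.04, adjusted p 9.1e-07; 0.99 in males and 0.08 in females) and Ptn, a growth factor gene that also led the gfp-positive unnamed class, by 0.57 (SE 0.08, adjusted p 0.0018). Whether the Ptn counted in neutrophils is free RNA from other cells was not measured. Aim2, a sensor of cytosolic DNA, fell by 0.68 (SE 0.12, adjusted p 0.0087), Cdc42bpg by 0.64 (SE 0.09) and Filip1l by 0.48 (SE 0.08). Of 8717 genes 50 passed (32 up, 18 down) and 1122 had an unadjusted p under 0.05. Helz2 (0.44, adjusted p 0.044) and Glis3 (-0.53, adjusted p 0.047) were past the threshold, but the Helz2 call ended without any 1 of mice m306, m307, m309, m319, m320, m315, m317, m311 and m313 (adjusted p up to 0.14) and the Glis3 call without any 1 of 10 mice. With the second barcode file alone the calls of Ptn, Aim2, Cdc42bpg and Filip1l ended (adjusted p up to 0.079). The count was 25 without mouse m306, 95 without m307, 28 without m309, 23 without m319, 27 without m320, 26 without m317, 32 without m311, 24 without m313 and 117 without m314.

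The type I interferon response in neutrophils was higher in LysM-cre mice in all 24 measured members on average over the sexes (median 0.42; 15 of 24 in females, median 0.03, and 24 of 24 in males, median 0.76), with log2 changes of 1.17 for Ifit3, 1.04 for Ifit1 and 0.76 for Cmpk2. None of the 24 passed over all genes, 16 passed adjusted over the list alone, and the camera adjusted p was 7.6e-11 (adjusted p = 0.318 with an estimated correlation). The neutrophil class holds 6 clusters whose shares were compared by exact permutation tests chosen after the data were examined, none past the threshold after adjustment. Ifit1, Ifit3, Rsad2 and Oasl1, members of the type I list, led 1 cluster, so its share is no separate evidence. It held 5.06% ± 1.44 of neutrophils in LysM-ctrl and 9.996% ± 4.53 in LysM-cre mice (SD, n = 6, exact p 0.03, adjusted p 0.06). A cluster led by Hcar2, Acod1 and Cxcl2 held 30.5% ± 5.21 and 21.9% ± 4.02 (exact p 0.025, adjusted p 0.06). A cluster led by Gpr27, Retnlg and Mmp8 held 15.8% ± 2.66 and 20.75% ± 2.02 (exact p 0.01, adjusted p 0.06). Within the single clusters the mean log2 CPM of the list differed between the genotypes by -0.081 to 0.218 (exact p 0.15 to 0.58). These differences were -0.247 to 0.007 in females and -0.052 to 0.509 in males, with 0.27 or more in males in all but the Ifit1 cluster. Over all neutrophils the difference was 0.477 (exact p 0.08), with 0.024 in females and 0.931 in males. List genes took part in forming the clusters, so the smaller differences within them do not tell a shift between cell states from a rise within them. The interferon gamma response was positive in 12 of 13 members (median 0.40), with 7 past the threshold adjusted over the list alone and a camera adjusted p of 7.8e-05 (adjusted p = 0.318 with an estimated correlation). Inflammatory macrophage genes, a list of cytokine and inflammasome genes, were lower in all 17 members (median -0.24), such as Nlrp3 (-0.24) and Cd80 (-0.29), and 2 passed adjusted over the list alone. The list passed camera (adjusted p 2.0e-04) with adjusted p = 0.318 with an estimated correlation, and not without mice m313 and m323 together (0.16). Lists that did not pass were tumour-associated neutrophil (6 of 21 positive, adjusted p 0.102), MHC class I (13 of 17), MHC class II (4 of 7, median 0.03, mean -0.03), chemokines (2 of 11), hypoxia and glycolysis (12 of 21) and dissociation stress (8 of 18).

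T cells were compared as a class of lymphocytes in the tumour-bearing bone. Whether they lay in the tumour or in the marrow was not measured. All 7 measured members of the regulatory T cell list were lower in LysM-cre mice (median -0.67), including Il2ra, the interleukin 2 receptor chain (-1.03, SE 0.38), the checkpoint receptor Ctla4 (-0.72, SE 0.30) and Tnfrsf18 (-0.67, SE 0.23). The LysM-ctrl males varied widely in these genes, with 143.57 ± 168.95 CPM of Il2ra and 382.95 ± 359.8 CPM of Ctla4 (SD, n = 3). Il2ra changed by -0.44 (SE 0.50) in females and -1.61 (SE 0.55) in males. The CD4-positive sub-cluster with Foxp3 was not smaller in LysM-cre mice (10.8% of T cells, 10.3% in LysM-ctrl). The Trdc sub-cluster, with Il2ra in 42.4% of cells, was 7.04% in LysM-cre and 12.04% in LysM-ctrl mice (exact permutation p 0.13). Whether these shares bear on the list was not tested. Eomes, a regulator of cytotoxic and memory T cells, had a log2 change of 1.06 (SE 0.26), and Cxcl10 one of 1.56 (SE 0.47). Gzmc, a granzyme, averaged -2.06 (SE 0.80) over opposite signs, with 0.32 (SE 0.86) in females and -4.43 (SE 1.27) in males, where LysM-ctrl males had 311.8 ± 481.6 CPM (SD, n = 3). None of these genes passed over all genes. 4 regulatory members passed adjusted over the list alone, and the list had a camera adjusted p of 0.144 (adjusted p = 0.739 with an estimated correlation). The other lists did not pass either, namely cytotoxicity (7 of 17 positive), T cell exhaustion (6 of 15), naive and memory T cell (10 of 13), type I interferon (6 of 10), interferon gamma (8 of 15), proliferation (7 of 22), oxidative phosphorylation (19 of 40), hypoxia and glycolysis (5 of 19, adjusted p 0.144) and dissociation stress (12 of 18). By edgeR 1 of 6379 genes passed, Gm47283 (4.45, SE 0.36, adjusted p 8.6e-07), chosen after its value was seen, and 472 had an unadjusted p under 0.05. DESeq2 called 6 genes and limma-voom 1, and the edgeR count was 2 without mouse m306 or m323.

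In the tumour class, cell-cycle genes were lower as a list in LysM-cre mice on average over the sexes, with the larger difference in males, where 2 LysM-cre mice were tested. All 23 proliferation genes were lower (median -0.48; positive in 5 of 23 in females, median -0.11, and in 0 of 23 in males, median -0.87), with log2 changes of -0.53 for Mki67, -0.81 for Ube2c and -0.60 for Nusap1 (females -0.10, -0.17 and 0.02, males -0.95, -1.44 and -1.23), and the list passed camera (adjusted p 1.5e-09) with adjusted p = 0.745 with an estimated correlation. Hypoxia and glycolysis was positive in 18 of 23 (median 0.33; 10 of 23 in females, median -0.12, and 23 of 23 in males, median 0.53), with 1.19 for Ero1l, an oxidase of protein folding (0.35 in females and 2.03 in males, with 266 ± 234 CPM in LysM-cre males, SD, n = 2), 1.00 for the angiogenic factor Vegfa and 0.52 for hexokinase Hk2. By the exact permutation test per mouse the differences between the sexes did not pass (p 0.22 for proliferation and 0.31 for hypoxia). Interferon gamma was positive in 15 of 19 (median 0.52), matrix remodelling in 16 of 20 (median 0.29), dissociation stress in 15 of 20 (median 0.16), and oxidative phosphorylation in 10 of 40 (median -0.08). The camera adjusted p was 0.023 for hypoxia and for interferon gamma, 0.030 for matrix remodelling and for dissociation stress, and 0.0033 for oxidative phosphorylation, each with adjusted p = 0.745 with an estimated correlation. These 5 calls ended without single mice, interferon gamma without m309 (0.66), m324 (0.068) or m314 (0.49), hypoxia without m307 (0.13), m324 (0.074), m315 (0.76) or m311 (0.83), matrix remodelling without m307 (0.058), m320 (0.062), m315 (0.56) or m311 (0.83), stress without m309 (0.092), m319 (0.058), m320 (0.25), m315 (0.17) or m311 (0.83), and oxidative phosphorylation without m311 (0.061). Hypoxia and dissociation stress turned downward without m311, and hypoxia and matrix remodelling with both gfp-positive clusters as 1 class (adjusted p 0.25 and 0.78). Not past the threshold were type I interferon (10 of 18 positive), MHC class I (9 of 16), MHC class II (5 of 8) and epithelial to mesenchymal transition (9 of 15, adjusted p 0.079, 2 up adjusted over the list alone). No list member passed over all genes, since edgeR called 0 of 12210 genes in 10 mice, with 1484 at an unadjusted p under 0.05, against 17 by DESeq2 and 0 by limma-voom. The edgeR count was 3 without mouse m317 and 433 without mouse m314. In males 8 genes passed, all lower in the 2 LysM-cre mice and named after their values were seen (Cyp51, Msmo1, Sc5d, Acat2, H2afx, Crabp1, Hist1h3e and Hist1h1e). In females 0 passed (717 at an unadjusted p under 0.05), and the interaction gave 0 (641).

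The gfp-positive unnamed class was compared in the same way, as a class that carried the added gfp sequence. Proliferation genes were positive in 3 of 23 (median -0.40), matrix remodelling in 3 of 20 (median -0.19), and hypoxia and glycolysis in 5 of 23 (median -0.14). Interferon gamma was positive in 16 of 21 (median 0.28; 2 of 21 in females and 21 of 21 in males), type I interferon in 17 of 26 (median 0.12), MHC class I in 11 of 15 (median 0.11), epithelial to mesenchymal transition in 10 of 15 (median 0.13) and dissociation stress in 15 of 19 (median 0.14). The camera adjusted p was 0.0024 for interferon gamma, 0.0049 for proliferation, 0.010 for type I interferon and for matrix remodelling, 0.022 for MHC class I, 0.023 for stress and 0.037 for hypoxia and for epithelial to mesenchymal transition, with adjusted p = 0.514 with an estimated correlation for each but hypoxia (adjusted p = 0.540). Oxidative phosphorylation (16 of 40) and MHC class II (4 of 9) did not pass, and Atp5b had a log2 change of -0.46 and Hk2 of 0.38. Over all genes 1 of 12849 passed by edgeR, Igkc, an immunoglobulin light chain gene of plasma and B cells (2.56, adjusted p 2.3e-05), named after its value was seen, with 1574 at an unadjusted p under 0.05, 53 by DESeq2 and 2 by limma-voom. How much of the Igkc in this class is free RNA from other cells was not measured. Single mice ended list calls for type I interferon (m309 and m313), MHC class I (m309, m319, m323, m313 and m314), hypoxia (m309, m319, m320, m323, m313 and m314), proliferation (m311), epithelial to mesenchymal transition (m307, m309, m319, m320, m323, m311 and m313) and stress (m309, m319, m320, m323, m311 and m313), with adjusted p up to 0.29, 0.29, 0.48, 0.081, 0.15 and 0.14. The gene count was 2 without mouse m307.

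Whether the genotype effect depends on sex was then read in monocytes and neutrophils, a comparison in which an additive pool effect cancels and whose genes were followed up after the data were examined. Tmsb4x in monocytes was 43528 ± 680 CPM in LysM-cre males, against 22576 ± 149 in LysM-ctrl males, 22109 ± 54.2 in LysM-cre females and 20760 ± 911 in LysM-ctrl females (SD, n = 3 each, share of all UMIs of the class). The male minus female genotype effect of Tmsb4x was 0.89 (SE 0.05, adjusted p 6.6e-08) in monocytes and 0.91 (SE 0.08, adjusted p 2.2e-05) in neutrophils. In monocytes Hccs (1.01, adjusted p 0.016), Msl3, of a chromatin complex (1.01, adjusted p 0.033), and the interferon-induced GTPase Gbp4 (5.13, adjusted p 0.048) passed as well. These 4 genes in monocytes (663 at an unadjusted p under 0.05) and 1 in neutrophils (537) were all that passed, and the fold of Gbp4 rests on group means of 0.272 to 2.47 CPM. Tmsb4x, Msl3 and Hccs lie in 1 segment of 2.113 Mb at the distal end of chromosome X (167207093 to 169320372, mm10) with 9 protein-coding genes, Tlr7 and Tlr8 among them. The measured segment genes had a median male log2 difference of 1.005 in monocytes (7 genes, females 0.013), 1.084 in neutrophils, 0.870 in T cells, 0.735 in B cells and 0.771 in macrophages. It was 0.078 in the gfp-positive unnamed class and -0.189 in the tumour class. No test was run on these medians themselves.

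**Figure D3:**
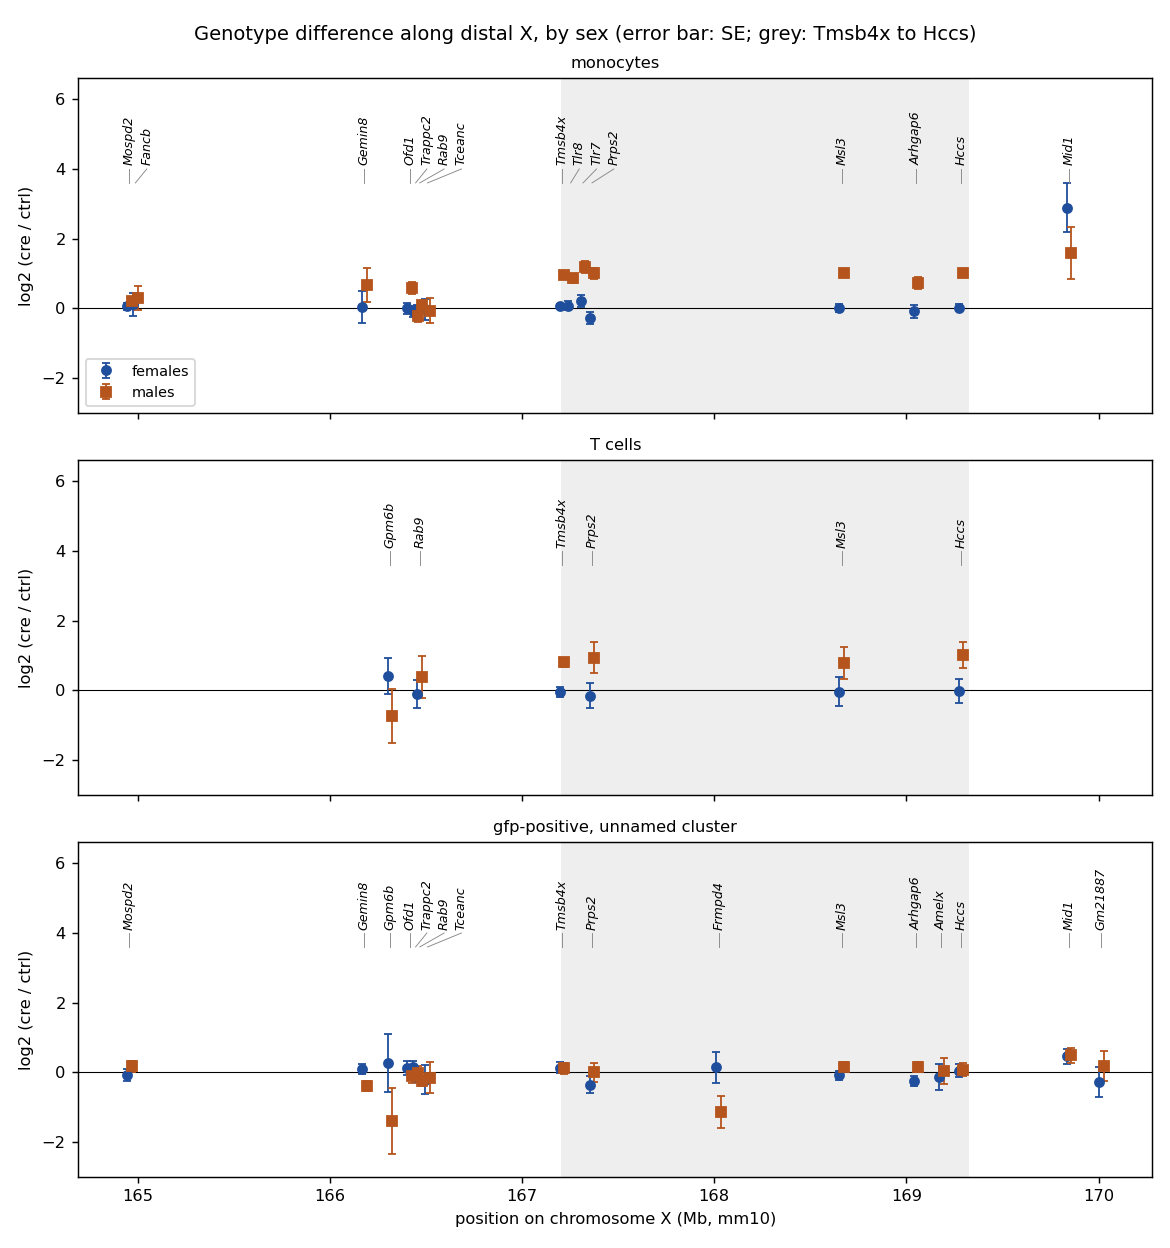
Log2 difference between LysM-cre and LysM-ctrl mice, with its SE, for measured genes at the distal end of chromosome X by position in Mb (mm10), in females (circles) and males (squares), in monocytes, T cells and the gfp-positive unnamed class. In the grey segment from Tmsb4x to Hccs the male median is 1.005 in monocytes, 0.870 in T cells and 0.078 in the gfp-positive unnamed class.

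In several classes interferon genes differed between the sexes in the same direction, a pattern chosen after the data were examined. In males all 26 type I genes of monocytes (median 0.65) and all 24 of neutrophils (median 0.76) were higher in LysM-cre mice, whereas in females 6 of 26 (median -0.08) and 15 of 24 (median 0.03) were. In T cells it was 10 of 10 in males (median 0.49) and 1 of 10 in females (median -0.42), and in macrophages the interferon gamma list had 17 of 17 (median 1.09) and 9 of 17 (median 0.03). In the gfp-positive unnamed class the interferon gamma list had 21 of 21 in males (median 0.95) and 2 of 21 in females (median -0.25). In the tumour class the genotypes overlapped in both sexes. Its mean log2 CPM of the type I list was 2.51 and 2.794 in LysM-cre females (LysM-ctrl 1.039 to 3.438). In males it was 2.17 and 2.313 (LysM-ctrl 1.871 to 2.273). For the interferon gamma list it was 1.732 and 3.162 in LysM-cre males (LysM-ctrl 1.563 to 2.0). The camera adjusted p in males was 4.9e-12 for type I genes in monocytes (adjusted p = 0.782 with an estimated correlation) and 1.4e-19 in neutrophils (adjusted p = 0.143 with an estimated correlation). The mean log2 CPM of both lists over monocytes, neutrophils and T cells was 5.27 ± 0.311 in LysM-cre males, 4.52 ± 0.235 in LysM-ctrl males, 4.73 ± 0.25 in LysM-cre females and 4.90 ± 0.134 in LysM-ctrl females (SD, n = 3 each). The male difference was 0.75 and the female difference -0.17, and their difference of 0.92 had a two-sided exact permutation p of 0.025 over 400 arrangements. Without mice m313 and m323 together it was 0.64 (exact p 0.08). For the type I list in 1 class alone the same exact permutation test gave p 0.09 in neutrophils and p 0.11 in monocytes.

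**Figure D4:**
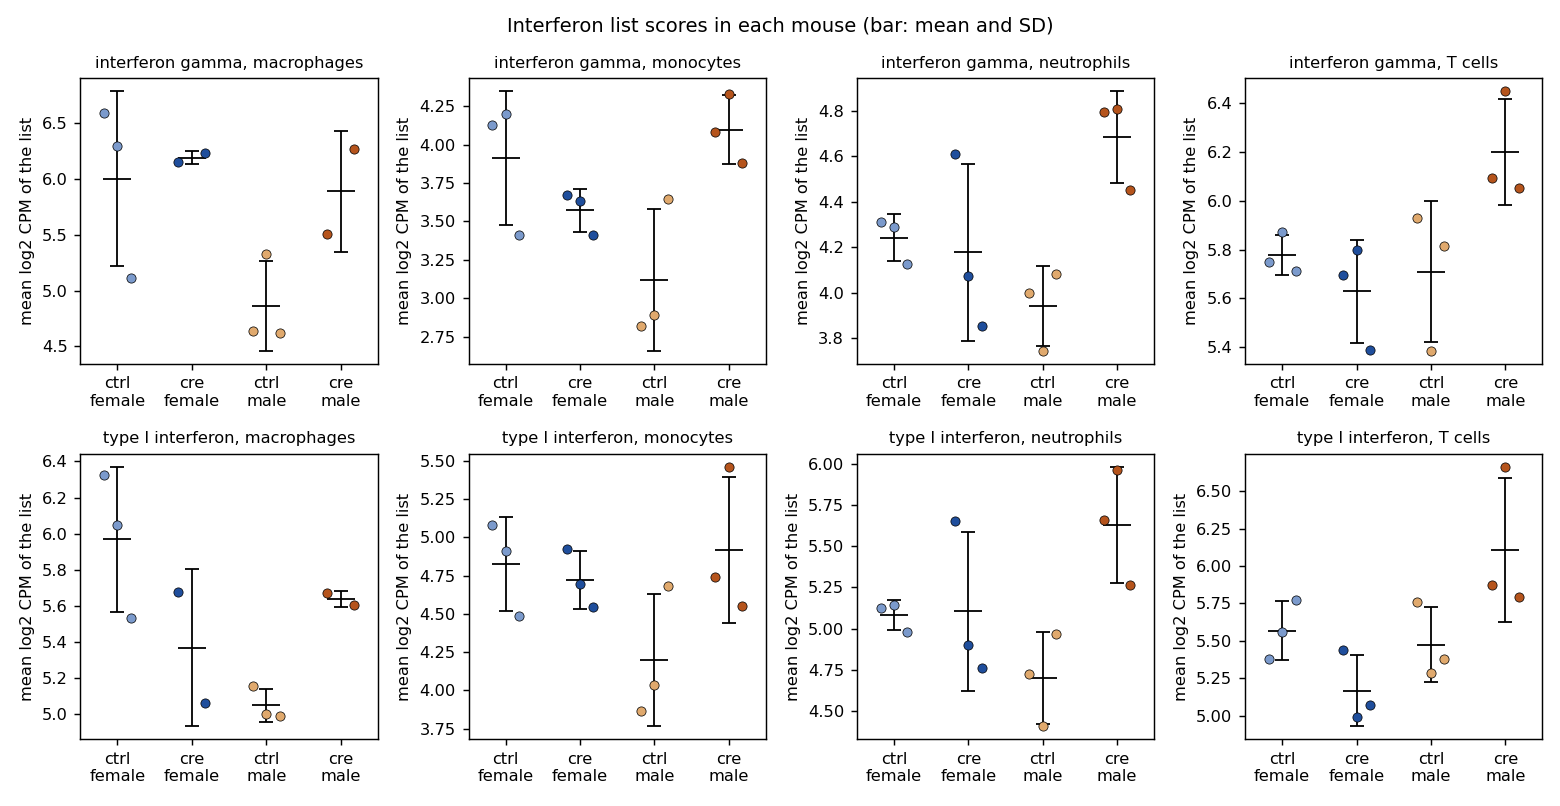
Mean log2 CPM of the interferon gamma list (upper panels) and the type I interferon list (lower panels) in macrophages, monocytes, neutrophils and T cells by group, with 1 point per mouse, the group mean and SD as a bar, and axes that do not start at 0. In neutrophils the type I list ranges from 5.26 to 5.96 in LysM-cre males and from 4.41 to 4.96 in LysM-ctrl males.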

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

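The tests of explanations and the counts of other splits of the mice in this part were chosen after the results were seen.

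The genotype effect in males exceeded that in females, by the interaction test of edgeR, for Tmsb4x (0.89), Hccs (1.01), Msl3 (1.01) and Gbp4 (5.13) in monocytes and for Tmsb4x (0.91) in neutrophils, all on the log2 scale. The fitted value of Gbp4 rests on group means of 0.272 to 2.47 CPM. The added gfp sequence, which no comparison between groups used, was found in 41.81% of the cells of the gfp-positive unnamed cluster and in 55.21% of those of the tumour cluster, against 30 of 40602 cells (0.074%) of the other named classes.

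The genes from Tmsb4x to Hccs on the distal X chromosome had higher levels in LysM-cre than in LysM-ctrl males, with a median log2 difference of 1.005 in monocytes. A difference between the library pools is argued against by the gfp-positive unnamed cells of the same pools, where the median was 0.078, and Esr1 deletion in LysM-expressing cells by T cells, where it was 0.87. An additional copy of the segment in the host cells of the LysM-cre males is a candidate explanation, since in monocytes the highest median of 6 neighbouring genes was 0.991 in the segment and 0.483 elsewhere in the genome, although in macrophages, B cells and basophils or mast cells 7, 15 and 1 windows elsewhere were as high. A translocation of distal X genes, Tlr7 included, onto the Y chromosome is known in mice, and whether these males carry one was not tested at the level of DNA. A response of the host cells to the deletion that is alike in both sexes is argued against by LysM-cre females, where the median in monocytes was 0.013 (highest gene 0.21, lowest gene in males 0.721). Gene dosage in these males, a strain difference between the lines and a response of host cells in males alone stay open.

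Interferon lists were higher in LysM-cre than in LysM-ctrl mice in males, with a difference of differences of 0.92 in the mean score. The exact permutation p for that difference was 0.025. It was between 0.01 (without m315) and 0.045 (without m320) with single mice left out and 0.08 without m313 and m323 together. This p cannot exclude a pool difference of 1 size in both sexes, because the score was composed after the pattern was seen. The same test did not pass for the type I list in neutrophils or monocytes alone. The higher levels of the X segment genes, the RNA sensor Tlr7 among them, and the Esr1 deletion cannot be told apart as sources, because a doubled Tmsb4x level and the genotype went together in 6 of 6 males. Neither explanation was tested further, and a pool effect, alike in both sexes or not, stays open.

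LysM-cre male m313 and LysM-cre female m323 held few tumour cells (0.106% and 0.075%, other mice 1.23% to 4.87%), few gfp-positive unnamed cells (0.957% and 0.842%, others 2.77% to 14.3%) and few macrophages (0.213% and 0.094%, others 0.821% to 3.34%), with more neutrophil precursors (33.0% and 32.8%, others 16.8% to 28.1%). A loss of bone and stromal cells during dissociation stays open, since both mice lay below the others in 2 of 5 such classes, endothelial cells (0.071% and 0.056%, others 0.183% to 0.689%) and osteoclasts (0 in both, others 0.051% to 0.496%), while mesenchymal cells (0.78% and 0.281%, others 0.178% to 1.37%), chondrocytes and pericytes lay within the range of the others. An exchange with a LysM-ctrl mouse is argued against by Lyz2 in monocytes, the higher of both being 7107.1 CPM, below the lowest LysM-ctrl mouse. A smaller tumour or a bone sampled away from it may account for these shares and was not tested, so no biological explanation was settled.

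Other splits of the mice into groups of the same sizes were tested in the same way as the real ones. For monocytes and genotype 1 of 100 splits, the real one, gave at least 135 genes (highest other 11), which argues against chance for this count. For neutrophils 2 of 100 gave at least 50, but the other one gave 203, so the count alone does not exclude chance. Of 200 possible splits 100 were run in each of these 2 classes. For macrophages and sex 1 of 60 splits gave at least 8 genes (highest other 3), which decides nothing, because 5 of the 8 are sex-linked genes that only the real split can call. For the 3 autosomal genes 2 of 60 gave at least 3 (highest other 3), so another split gave as many. The sex-linked genes called in the real split also ease its adjustment of p, so this count does not exclude chance. By the count alone it cannot be excluded for macrophages and genotype, where 5 of 100 splits gave at least 5 genes (highest other 17), for T cells (8 of 100 gave at least 1, highest other 34), for the gfp-positive unnamed class (8 of 100 gave at least 1, highest other 6), for the interaction in monocytes (8 of 100 gave at least 4, highest other 48), for the interaction in neutrophils (18 of 100 gave at least 1, highest other 121) or for the tumour class, whose count of 0 was met by 100 of 100 (highest other 5). The splits with 203 genes in neutrophils, 34 in T cells and 48 and 121 in the interactions called several times the real count, and what sets these splits apart was not tested. The interaction count in monocytes does not bear on Tmsb4x singly, which had 42786 to 44123 CPM there in the 3 LysM-cre males and 19752 to 22721 CPM in the other 9 mice (interaction adjusted p 6.6e-08).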

How the results depend on the processing

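The counts without mice m313 and m323, with both gfp-positive clusters as 1 class, and of lists by an exact permutation test per mouse, and the Esr1 share expected over all thinnings, were chosen after the data were seen. Class shares kept their side of the threshold in all 121 comparisons other than those named below, and 3 of these differences, which had not passed, turned sign. Of 6939 values of named genes under other settings, 6594 kept their side of the threshold (68 of them, not past it, turned sign), 168 newly passed, 177 no longer passed and 0 reversed. Of 1068 list results, 889 kept their side (75 of them, not past the threshold, turned sign), 47 newly passed, 128 no longer passed and 4 reversed. The 2 share differences between the sexes became 1 by edgeR on cell counts and 0 at Leiden resolution 2.0, with barcode file 1 only, with barcode file 2 only and without m313 and m323, where 120 arrangements keep 2 classes from passing (0 to 2 with single mice left out). In that order of settings after edgeR, the T-cell difference was -0.4, -1.286, -0.85 and -1.041 points (single mice -1.203 to -0.929), and the natural killer difference -1.285, -0.456, -0.616 and -0.62 points (single mice -0.633 to -0.442). At Leiden resolution 0.5 the gene counts were 2 for macrophages and genotype (5 as reported), 3 in females (5), 3 for the interaction (0), 84 for monocytes (135), 218 for neutrophils (50) and 52 for the tumour class (0), which there included the gfp-positive unnamed class, so that class has no value. At Leiden resolution 2.0 they were 3 for macrophages and genotype, 1 in females, 4 in males (12), 1 for the interaction, 5 for T cells (1) and 578 for the tumour class. With barcode file 1 only they were 2 for macrophages and genotype, 1 in females, 2 in males, 65 for monocytes and 1 for the tumour class, and with barcode file 2 only 8 for macrophages and genotype, 7 in males, 5 for macrophages and sex (8), 52 for monocytes, 16 for neutrophils and 2 for the gfp-positive unnamed class (1). Fewer cells per mouse are part of these last settings. Leaving out cells with a Scrublet score above 0.25 gave 3 for macrophages and genotype, as did at least 10 counts per mouse. DESeq2 gave 10 for macrophages and genotype, 3 for the interaction, 13 for sex, 226 for monocytes, 100 for neutrophils, 6 for T cells, 17 for the tumour class and 53 for the gfp-positive unnamed class, and limma-voom gave 3 for macrophages in females and 2 for the gfp-positive unnamed class. With no filter on low counts the counts were 69 for macrophages and genotype, 51 in females, 85 in males, 55 for the interaction, 91 for sex, 489 for monocytes, 3.2e+02 (rounded to 2 digits) for neutrophils, 61 for T cells, 381 for the tumour class and 88 for the gfp-positive unnamed class. The male mice alone gave 24 for macrophages in males. Without m313 and m323 there were 54 for monocytes, 33 for neutrophils and 2 for T cells, and with both gfp-positive clusters as 1 class 41 for the tumour class. With single mice left out the counts ranged from 3 to 11 for macrophages and genotype, 2 to 7 in females, 3 to 17 in males, 0 to 7 for the interaction, 6 to 18 for sex, 40 to 158 for monocytes, 23 to 117 for neutrophils, 1 to 2 for T cells, 0 to 433 for the tumour class and 1 to 2 for the gfp-positive unnamed class. The 23 of 71 class and list pairs past camera became 0 with an estimated correlation, 0 by fry and 0 by the exact permutation test per mouse. In that last test 1 list alone at the smallest possible p could pass only in neutrophils, given the number of lists per class. With both gfp-positive clusters as 1 class the tumour lists of hypoxia (adjusted p 0.2501) and matrix remodelling (adjusted p 0.7772) turned downward. The adjusted p of tumour hypoxia ranged from 2.536e-05 without m317 to 0.8269 without m311, where it reversed, and that of tumour dissociation stress from 5.132e-05 without m314 to 0.8269 without m311, where it reversed. The difference in the share of macrophages with an Esr1 UMI ranged from -4.211 points without m317 to -2.609 without m324 (-3.275 with all mice) and was -2.346 points with the stricter filter, -2.433 without m313 and m323, -0.89 as the share expected over all thinnings and 2.622 without thinning. The cause was not tested for any of these changes. No paired analysis was possible because mouse numbers differ between groups. Depth limits the macrophage comparison, since m313 and m323 had fewer than 20 macrophages and the thinned Esr1 share of single mice rests on as few as 4 cells.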

Other observations

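Other blood cells also differed between the genotypes by edgeR. Neutrophil precursors had 33 genes past the threshold (17 up, 16 down), plasmacytoid dendritic cells 18 (10 up, 8 down), conventional dendritic cells 10 (4 up, 6 down), B cells 8 (3 up, 5 down), basophils or mast cells 4 up and haematopoietic progenitors 3 up. Lyz2 fell in conventional dendritic cells (-1.23), neutrophil precursors (-1.09) and plasmacytoid dendritic cells (-1.52), and in 6 of 12 classes in all. Hist1h2ap rose in 7 of 10 classes and Tmsb4x in 7 of 12. Gm47283, a gene model annotated on the Y chromosome, rose in 9 of 12 classes in mice of both sexes. In monocytes it had 38.65 to 66.51 CPM in LysM-cre males and 39.86 to 94.66 CPM in LysM-cre females. Its level thus did not follow the sex of the host, and it cannot be read as a transcript of male cells. In the gfp-positive unnamed class and the tumour class it was high in both genotypes, with 191.7 and 217.2 CPM in LysM-ctrl females. Igkc rose in 4 of 9 classes and Gm10076 in 5 of 12, while Gm42418 fell in 5 and Cmss1, Gphn and Lars2 in 4 each. These genes were chosen after their values were seen. How much of these transcripts, Lyz2 and Igkc included, is free RNA from other classes was not measured.

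In both gfp-positive clusters Xist, the RNA of the inactive X chromosome, was found in 84.3% to 91.3% of cells whether the host was female or male, and transcripts of Y-linked genes had 2.78 to 4.94 CPM. In the 17 host classes of male mice Xist was found in 2.75% to 15.49% of cells, and Y-linked genes had 175.63 to 360.58 CPM. A host origin of the gfp-positive unnamed cells of male mice is argued against by Xist in 91.29% of them, with Y-linked genes at 4.94 CPM, close to the tumour class (85.71% and 4.57 CPM). This test was chosen after the values were seen, does not itself name the cells and cannot decide in female mice. LLC1 is the only source of cells other than the host that is described for these mice. The tumour class may therefore hold only a part of the tumour cells. The deposited features held an added esr1 sequence with 1 UMI in the 24 files and an added GFP sequence with 0 UMIs, beside the gfp sequence with 3224. B cells made up 5.84% of cells in LysM-cre female m323, against 0.371% to 3.52% in the 10 mice other than m313 and m323.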
